A study of Homo sapiens with 40 samples.

How the data were processed

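Small RNA was sequenced from 15 human whole lung tissue samples in 40 libraries. Per the labels, libraries were made with the TruSeq Small RNA protocol, indexed at PCR, pooled in equal amounts, gel purified together per pool and read on a HiSeq 2000. The lanes used here held 1, 3, 6, 9 or 12 libraries, with or without PhiX. The authors' processing notes name Bowtie 0.12.7, bedtools 2.9.0 and the build hg19, and the deposited table names mature miRNAs of miRBase 18 in each of its 2104 rows, 1 row per mature miRNA and locus, with 1919 names of which 144 stand on several loci. Adapter trimming, mismatches and the treatment of reads that map to several loci are not given in the sources used here.

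The deposited values are log2 values, although the file's name gives RPM: each is log2 of (reads + 1) over the library's divisor in megareads (1e6 reads), by the authors. This was tested on the values. In each column 2 to the power of the value minus the column minimum was whole in 100% of entries (tolerance 0.001), so whole reads per locus and the divisor of each library were computed back. The divisor was taken as the library's miRNA reads; reads summed over names came to between 1.004 and 1.006 times the divisor. RPM, reads-per-million, was computed as reads over the divisor in megareads. The tests were planned for a table of RPM, and RPM so computed was used. Depth ran from 2.22 to 45 megareads of miRNA per library. A count of 0 allows up to 3 reads, given as RPM over the libraries of a group, and this covers counting error only. Levels of miRNAs at 0 in the other lane are means over libraries instead, and can rest on few reads.

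Libraries were grouped by lane and tissue sample letter from the labels. Libraries with the same letter have the same tissue sample and index in the labels, so tissue sample was a block in every lane comparison. The fits, lists, alternatives and the rule for named miRNAs were fixed before the data were examined, apart from those named below. Differences between lanes were tested with limma 3.58.1 in R 4.3.3 on log2(RPM + 1), with a variance trend, on loci with a mean of at least 1 RPM in the libraries of the fit, two-sided, at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were 12-plex with 6-plex and 9-plex with 6-plex (E to J), 12-plex with 3-plex (B to D), and PhiX with no PhiX at 6-plex and 3-plex. Each p and SE rests on how the difference between 2 lanes varied over tissue samples, moderated by a variance trend over loci. Reads of the 2 lanes differed beyond counting error in every pair (chi-square per degree of freedom 2.28 to 6.78). That chi-square includes the difference between lanes and does not measure the residual spread. Whether each lane's pool was made and gel purified anew is not given in the sources used here. As each condition was 1 lane, differences between lanes are part of every effect. The 2 PhiX effects, and the 12-plex and 9-plex effects, were compared by interaction terms. Tissue samples E to J were compared over lanes 5 to 8 by limma's moderated F test with lane as a covariate.

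The 12 fixed lists were epithelial, ciliated epithelial, smooth muscle and mesenchymal, striated muscle, endothelial, leukocyte, erythroid, let-7 family, miR-17-92 and paralog clusters, miR-29 and miR-30 families, injury and hypoxia, and other tissues (liver, brain, pancreas). Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. Named miRNAs were, per lane comparison, the 10 highest and 10 lowest changes among those called and moved the same way in every pair, the 2 most abundant tested members of each list and any member called. For tissue samples they were the 20 with the largest SD, the 10 with the smallest SD at 100 RPM or more, and the 3 most abundant of each list. The 10 most abundant miRNAs, and for detection the 5 most abundant at 0 in the other lane, were also named; the report prints a selection of the list members. miR-1248 in the 12-plex and 6-plex comparison, and the miRNAs given for tissue sample A, were chosen after their values were seen.

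Detection was the number of names with at least 1 read, compared within pairs by an exact sign-flip permutation test, two-sided. Correlations were permuted 100000 times within lanes, one-sided. Thinning gave the number of names expected to keep at least 1 read when each read of the deeper library is kept with the ratio of the pair's depths as its probability. Loci were placed on small nucleolar RNA and host genes with GENCODE 29 and RefSeq names, used for names and hairpin GC content only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.

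The fits were tested on simulated data with known changes. Of loci changed 1.5-fold in the simulations, 76.0% to 94.0% were recovered across the 5 lane comparisons, and of the smallest simulated change (5%, over the median size of the real calls) 16.0% to 36.0%, with 0.862% to 5.30% false calls and 0 calls with no change; the F test recovered 80.3% with 1.85% false calls. Without the variance trend the simulated calls went from 133 to 132 (12-plex and 6-plex) and, at most, from 126 to 93 (12-plex and 3-plex), where the real calls went from 53 to 3 and from 41 to 0. The simulations drew noise separately for each locus and so did not behave like the data. Their false call rates may not hold for the small real shifts. In 1 list simulation, of the 12-plex and 6-plex comparison, a list moved 1.1-fold was called and 0 of 11 others were. The real list medians of that comparison were smaller, from -0.044 to 0.036 log2. The simulation does not show whether list shifts of that size would be found. Fixed alternatives were pseudocounts of 0.1 and 5 RPM, no filter or a mean of at least 10 RPM, median-ratio rescaling, no variance trend, no tissue sample block, leaving out each tissue sample, and other detection thresholds. Alternatives added after seeing the data were 1 row per mature name, the deposited log2 values, voom on whole reads, detection by locus, at least 5 reads, and leaving out F from the comparison of tissue samples. Lane 4, a control lane of PhiX, was not used here.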

Results

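MicroRNAs (miRNAs, short RNAs that repress messenger RNAs) were counted by small RNA sequencing in human whole lung tissue. The 40 libraries came from 15 tissue samples, called A to O here, and were run in 7 lanes with 1 to 12 libraries per lane. Lane 1 held A alone. Lanes 2 and 3 each held B to D (3-plex), and lanes 5 and 6 each held E to J (6-plex). Lane 7 held E to M (9-plex) and lane 8 held A to J, N and O (12-plex). PhiX, a phage DNA library often added to balance base composition, was added to lanes 3, 6 and 7. The same letter in several lanes is 1 tissue sample with the same index read again. The p values and SEs of lane comparisons rest on how a lane difference varied over these libraries, moderated over loci. They measure neither a spread between people nor one between replicate lanes. Each condition was 1 lane, so the number of libraries and PhiX cannot be separated from the lane.

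The mean number of miRNA reads per library, in megareads (1e6 reads), was 45 in lane 1 (1 library) and 18.8 ± 2.12 (SD, n = 3) in lane 2. Lane 3 had 18.8 ± 2.58 (SD, n = 3), lane 5 had 9.53 ± 3.92 (SD, n = 6) and lane 6 had 8.96 ± 3.65 (SD, n = 6). Lane 7 had 5.58 ± 2 (SD, n = 9) and lane 8 had 4.93 ± 1.47 (SD, n = 12). Single libraries ranged from 2.22 megareads in lane 8 to 45 megareads in lane 1. Of 1919 mature miRNA names in the file, 1455 had reads in at least 1 library, 423 had reads in every library and 464 had none. Levels are given in reads-per-million (RPM) of each library's miRNA reads, and fitted changes, percent changes included, are of RPM + 1. The upper limits given for 0 reads cover counting error only, since reads without molecular identifiers are not independent molecules.

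The most abundant miRNA was miR-143-3p (chromosome 5, 148808541 to 148808561, hg19), a smooth muscle miRNA, with 21.4% ± 5.82 of reads (SD, n = 15 tissue samples). It was followed by miR-26a-5p with 14.8% ± 6.5, miR-10a-5p with 6.71% ± 2.04 and let-7a-5p, of the let-7 family, with 6.68% ± 1.54 (SD, n = 15 each). miR-30a-5p had 6.65% ± 2.44 of reads, and miR-146b-5p, an inflammation-related miRNA of leukocytes and other cells, had 5.89% ± 2.64 (SD, n = 15 each). miR-181a-5p had 4.24% ± 1.22, miR-148a-3p 2.77% ± 1.99, miR-10b-5p 2.77% ± 1.72 and let-7f-5p 2.52% ± 0.593 (SD, n = 15 each).

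**Figure D1:**
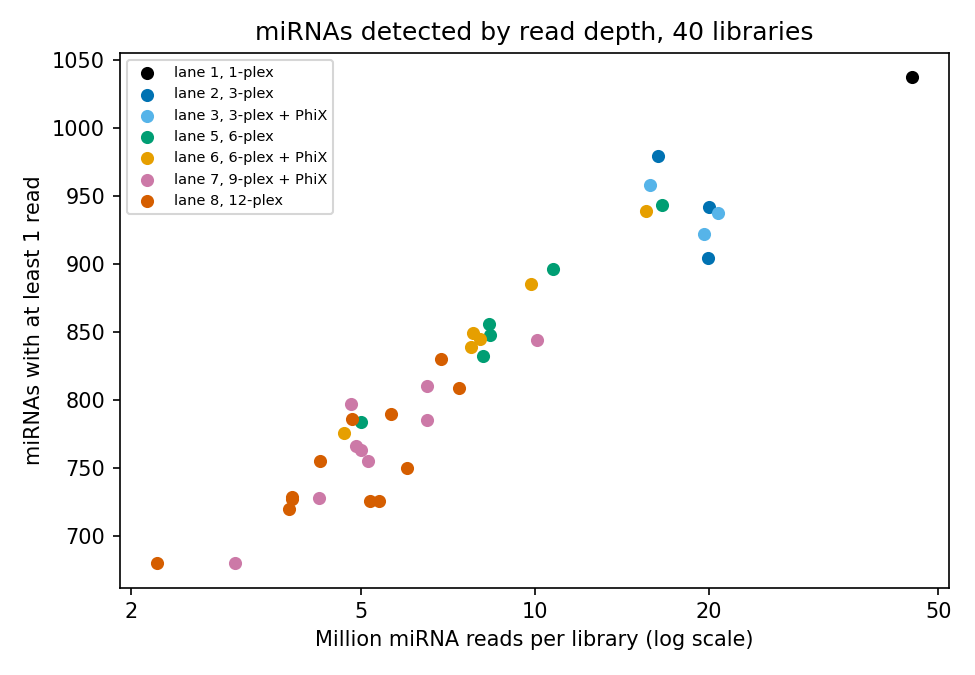
Number of miRNA names with at least 1 read in each library against its miRNA reads in megareads (log axis), each point 1 of the 40 libraries, marked by lane. The number detected was 1037 in the 1-plex library at 45 megareads and averaged 752.3 in the 12-plex lane at 4.93 megareads.

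The first comparison set the 12-plex lane against the 6-plex lane without PhiX for the same 6 tissue samples (E to J), and asked what adding libraries to a lane does to detection and measured levels. miR-3607-5p, whose locus lies on the small nucleolar RNA gene SNORD138 (chromosome 5, 85916325 to 85916346), went from 19.2 RPM ± 10.8 to 2.62 RPM ± 1.96 (SD, n = 6) and fell by 2.50 ± 0.109 on the log2 scale (SE; limma adjusted p = 2.3e-10). miR-3653, on SNORD125 in an intron of AP1B1 (chromosome 22, 29729165 to 29729182), went from 3.3 RPM ± 1.01 to 0.997 RPM ± 0.318 (SD, n = 6) and fell by 1.09 ± 0.142 (SE; limma adjusted p = 4.5e-05). miR-1291, on SNORA2C in an intron of KANSL2 (chromosome 12, 49048277 to 49048300), went from 3.4 RPM ± 2.26 to 11.3 RPM ± 8.72 (SD, n = 6) and rose by 1.40 ± 0.148 (SE; limma adjusted p = 5e-06). Each of these moved the same way in 6 of 6 tissue samples. miR-1248, on SNORA81, had a log2 change of -1.29 that passed the test without going the same way in every tissue sample, and no other of the 53 loci called changed by over 1 log2 unit. The other 2 tested loci on small nucleolar RNA genes, miR-664-5p at -0.03 and miR-664-3p at 0.06 log2, were not called.

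Most of the 53 called loci (18 higher, 35 lower, of 510 tested, 45 names) were abundant miRNAs with small shifts, with a median size of 0.041 on the log2 scale. miR-486-5p, a miRNA of red blood cells, rose by 5.44% and miR-423-5p by 5.63%. miR-186-5p rose by 4.76%, miR-30e-3p by 4.66%, miR-191-5p by 3.35%, miR-146a-5p by 2.79%, miR-182-5p by 2.72%, miR-146b-5p by 2.7% and miR-151a-3p by 2.4%. miR-28-5p fell by 11.3%, miR-144-3p by 6.47%, miR-425-5p by 6.3%, miR-199a-3p and miR-199b-3p by 4.23% each, miR-107 by 4.2%, miR-23b-3p by 4.05% and miR-451a by 3.98%. The miR-199a-3p and miR-199b-3p values were equal and are the same measurement under both names. Of the erythroid list (5 loci tested), miR-486-5p rose while miR-451a and miR-144-3p fell, with 3 called when adjusted over the list alone. Of the smooth muscle and mesenchymal list (22 loci), 6 fell, miR-143-3p by 0.02 ± 0.002 log2 (SE) among them, and 2 rose, miR-10b-5p and miR-145-5p, with 10 called when adjusted over the list alone and 0 under median-ratio rescaling. Of the let-7 family (21 loci), 7 fell, with 7 called when adjusted over the list alone; its median of -0.011 flipped to 0.008 under median-ratio rescaling, with 0 members called.

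In the epithelial list (14 loci), miR-182-5p rose and miR-141-3p and miR-200a-3p fell, with 3 called when adjusted over the list alone. In the ciliated epithelial list (8 loci), miR-449c-5p fell by 0.29 ± 0.081 log2 (SE), with 1 called over the list alone, and miR-34c-5p had a change of 0.03 ± 0.021. miR-449c-5p did not fall in every tissue sample, and F and G averaged only 10.1 and 5.74 RPM of it over lanes 5 to 8. The leukocyte list (16 loci) had miR-146b-5p and miR-146a-5p higher, with 2 called over the list alone, and the miR-17-92 clusters (18 loci) had both miR-92a-3p loci higher, with 3 called over the list alone. The miR-29 and miR-30 families (20 loci) had miR-30e-3p and miR-30d-5p higher, with 2 called over the list alone, and the injury and hypoxia list (10 loci) had miR-21-5p lower, with 1 called over the list alone. Under median-ratio rescaling the epithelial, leukocyte, miR-17-92 and injury lists had 0 members called, the erythroid and the miR-29 and miR-30 lists 1 higher each, and the ciliated list 1 lower. No striated muscle, endothelial or other-tissue miRNA was called, also when adjusted over the list alone. No list moved as a set by camera (12 lists, smallest adjusted p = 0.6), and the medians of the epithelial, striated muscle, endothelial, leukocyte and miR-29 and miR-30 lists differed in sign from their test. Under median-ratio rescaling the medians of the epithelial, endothelial, leukocyte, injury and miR-29 and miR-30 lists turned from negative to positive. Without the variance trend 3 loci were called (miR-1291, miR-3607-5p and miR-3653), and without the tissue sample block 2 (miR-3607-5p and miR-3653). Under median-ratio rescaling 12 loci were called, 7 higher and 5 lower, against the 18 and 35 above.

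Fewer miRNAs were detected at 12-plex, with 741.8 ± 47.2 names per library against 859.8 ± 54.6 at 6-plex (SD, n = 6). The difference was -118.0 ± 11.3 (SD, n = 6; lower in 6 of 6; exact sign-flip test, two-sided, p = 0.031, the smallest possible), at 0.452 times the reads. In all, 173 miRNAs with reads at 6-plex had 0 reads in all 6 libraries at 12-plex, which allows up to 0.116 RPM over the group, and 53 showed the reverse. The most abundant of the 173 were miR-1913 at 0.207 RPM at 6-plex, miR-4640-3p at 0.174, miR-3144-3p at 0.141, miR-4753-5p at 0.133 and miR-1268b at 0.123 RPM. These are means over libraries and rest on 7, 10, 7, 4 and 5 reads in all, those of miR-4753-5p from 1 library. They cannot be set directly against the limit over the group. Counting only names with at least 1 RPM gave 457.2 at 12-plex against 450.7 at 6-plex, a difference of 6.5 with the opposite sign.

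**Figure D2:**
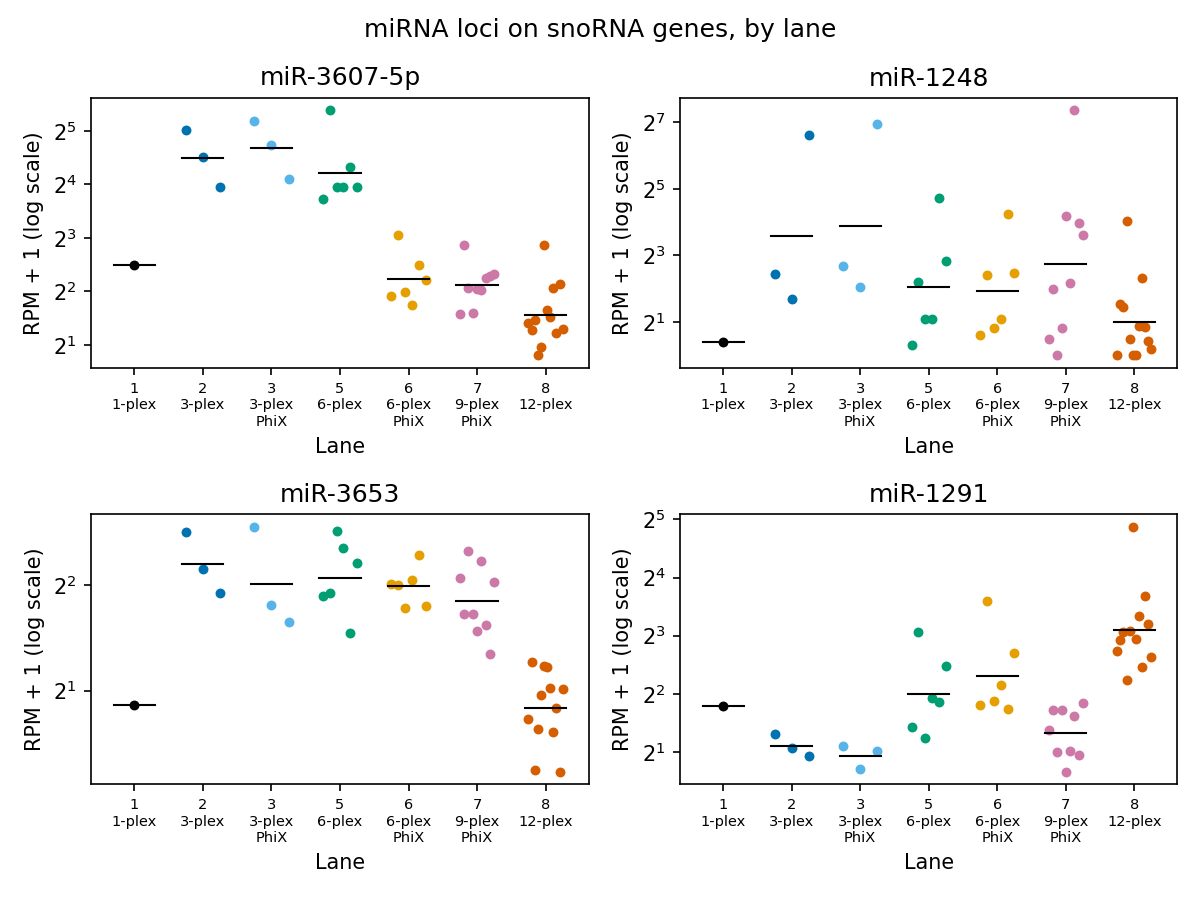
Level of miR-3607-5p, miR-1248, miR-3653 and miR-1291, all on small nucleolar RNA genes, in every library by lane (RPM + 1, log axis), with bars at the mean of log2(RPM + 1) per lane. Lanes hold different tissue samples, so only points of the same tissue sample can be compared across lanes. miR-3607-5p averaged 19.2 RPM in lane 5 and 3.92 RPM in lane 6, which held the same 6 tissue samples.

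The second comparison set the 9-plex against the 6-plex lane, both with PhiX, for E to J. miR-1291 went from 4.59 RPM ± 3.4 to 1.47 RPM ± 0.725 (SD, n = 6) and fell by 1.06 ± 0.166 on the log2 scale (SE; limma adjusted p = 9.8e-05), the opposite of its change at 12-plex. miR-186-5p rose by 5.12% (0.07 ± 0.009 log2, SE; limma adjusted p = 9.8e-07), miR-375, an epithelial and neuroendocrine miRNA, by 4.28%, and miR-146a-5p by 3.18%. miR-378a-3p fell by 6.76% (0.10 ± 0.012 log2, SE; limma adjusted p = 9.8e-07), and miR-200b-3p, of the epithelial miR-200 family, by 6.38%. Each of these went the same way in 6 of 6 tissue samples.

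The test called 32 loci (10 higher, 22 lower, of 516 tested, 27 names), with a median size of 0.041 log2. Among the rest, miR-4510 rose by 35.3% from 2.52 RPM ± 1.15 to 3.71 RPM ± 1.25 (SD, n = 6), miR-29a-3p by 2.75%, miR-21-3p by 2.56%, miR-142-5p by 2.22%, miR-146b-5p by 1.6% and miR-30a-5p by 1.21%. miR-28-5p fell by 6.74%, miR-660-5p by 6.06%, miR-103a-3p by 3.74%, miR-140-3p by 3.67%, miR-23b-3p by 3.52%, let-7d-5p by 2.86% and miR-199a-3p by 2.8%. In the leukocyte list (16 loci), miR-146a-5p, miR-142-5p and miR-146b-5p rose and none fell, with 3 called when adjusted over the list alone. In the smooth muscle and mesenchymal list (22 loci) 4 fell, those of miR-199a-3p, miR-199b-3p and miR-10b-5p, with 7 called over the list alone, while median-ratio rescaling gave 0 lower and 1 higher. In the let-7 family (21 loci) 5 fell, with 8 called over the list alone, and its median of -0.019 flipped to 0.005 under median-ratio rescaling, with 0 called. In the miR-29 and miR-30 families (20 loci) miR-30a-5p and miR-29a-3p rose, with 2 called over the list alone; as a set they had a camera adjusted p of 0.069, and 0.7 with an estimated correlation.

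The epithelial list (14 loci) had miR-375 higher and miR-200b-3p lower (2 over the list alone), the ciliated list (8 loci) had miR-449c-5p lower at -0.14 ± 0.04 log2 (SE, 1 over the list alone), though not in every tissue sample, and the injury and hypoxia list (10 loci) had miR-21-3p higher (2 over the list alone). Under median-ratio rescaling 5 rose in the leukocyte list, 5 in the miR-29 and miR-30 families and 2 in the endothelial list, the epithelial and injury lists had 1 higher and 1 lower each, and the ciliated list 1 lower. No striated muscle, erythroid, miR-17-92 or other-tissue member was called either way of adjusting, and the endothelial list (9 loci) had 0 called over all loci and 1 over the list alone. No list was called as a set, and for the leukocyte, miR-17-92 and injury lists the mean was negative where the median and the test were positive. Without the variance trend or without the tissue sample block, limma called 0 loci here (91 loci had an unadjusted p under 0.05 with both, and voom called 38), and without tissue sample F it called 20. Median-ratio rescaling called 34 loci, 29 higher and 5 lower, so which way most loci went depended on the scaling.

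Across E to J, 4 names rose in both this and the 12-plex comparison and 9 fell in both, where 1.68 and 4.06 would be shared if calls fell evenly within classes of RPM. The shared names were miR-186-5p, miR-146a-5p, miR-146b-5p and miR-191-5p among the higher, and let-7a-5p, let-7c, miR-23b-3p, miR-28-5p, miR-101-3p, miR-103a-3p, miR-199a-3p, miR-199b-3p and miR-449c-5p among the lower. miR-199a-3p and miR-199b-3p had equal values at 12-plex and 6-plex, so the 9 count the same measurement under both names. miR-1291, miR-10b-5p and miR-148a-3p were called in opposite directions. Across the 72 loci over 1000 RPM the log2 changes had a Pearson's r of 0.587 and a Spearman's rho of 0.611, and across all 509 loci an r of -0.015; loci are not independent replicates, and both comparisons share tissue samples. The 12-plex and 9-plex effects differed at 20 of 512 loci in a limma test of the difference.

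At 9-plex 769.7 ± 55.6 miRNA names were detected per library against 855.5 ± 54 at 6-plex (SD, n = 6). The difference was -85.8 ± 8.4 (SD, n = 6; lower in 6 of 6; exact sign-flip test, two-sided, p = 0.031, the smallest possible), at 0.644 times the reads. Of the miRNAs seen at 6-plex, 164 had 0 reads in the 6 libraries at 9-plex, which allows up to 0.0866 RPM over the group, and 72 showed the reverse. The most abundant of the 164 were miR-2681-3p at 0.172 RPM, miR-4726-5p at 0.134, miR-4522 at 0.111, miR-4711-5p at 0.107 and miR-541-3p at 0.0956 RPM, as means over libraries. miR-2681-3p had 9 reads and the others 5 each. Counting only names with at least 1 RPM gave a difference of 3.8, with the opposite sign, and requiring at least 5 reads, chosen after seeing the data, one of -52.0.

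The third comparison set the 6-plex lane with PhiX against the 6-plex lane without it, and asked whether the PhiX lane gave other levels for E to J. miR-3607-5p went from 19.2 RPM ± 10.8 to 3.92 RPM ± 1.82 (SD, n = 6) and fell by 1.99 ± 0.096 on the log2 scale (SE; limma adjusted p = 9.4e-13; lower in 6 of 6). The abundant erythroid miRNAs parted, with miR-451a lower by 0.07 ± 0.007 log2 (SE; limma adjusted p = 2e-07) and miR-486-5p higher by 0.05 ± 0.006 (SE; limma adjusted p = 1e-06). miR-126-5p, from an intron of the endothelial gene EGFL7, fell by 5.01%, and its partner arm miR-126-3p had a log2 change of 0.02 ± 0.008 (SE) that did not pass. miR-125b-5p rose by 5.23% and miR-28-5p fell by 8.3%.

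The test called 61 loci (22 higher, 39 lower, of 514 tested, 52 names), with a median size of 0.054 log2, and only miR-3607-5p passed 1 log2 unit. miR-660-5p rose by 5.06%, miR-1307-5p by 4.58%, miR-423-5p by 3.8%, let-7b-5p by 3.08%, miR-148a-3p by 2.81%, miR-10b-5p by 2.22%, let-7i-5p by 1.78% and miR-146b-5p by 1.68%. miR-449c-5p fell by 9.72%, miR-145-3p by 7.63%, miR-181c-5p by 5.08%, miR-340-5p by 4.69%, miR-374b-5p by 4.66% and miR-130a-3p by 4.58%. The log2 change of miR-449c-5p was -0.15 with G and -0.08 without it, G having 5.74 RPM of it. In the endothelial list (9 loci) miR-126-5p, miR-130a-3p and miR-221-3p fell and none rose (3 called over the list alone; 2 fell under median-ratio rescaling). In the let-7 family (21 loci) 7 rose and none fell, let-7b-5p by 0.04 ± 0.006 log2 (SE) the most, with 8 called when adjusted over the list alone and 1 higher under median-ratio rescaling. In the smooth muscle and mesenchymal list (22 loci) 3 rose and 5 fell (10 over the list alone), and in the leukocyte list (16 loci) miR-146b-5p and miR-146b-3p rose while 3 loci of miR-142-5p and miR-181a-5p fell (5 over the list alone).

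The miR-29 and miR-30 families (20 loci) had miR-30a-3p, miR-29a-3p and miR-30a-5p lower (7 over the list alone; 1 under median-ratio rescaling), and the miR-17-92 clusters (18 loci) had miR-25-3p and miR-363-3p lower (2 over the list alone), with the median of -0.001 flipping to 0.005 under that scaling. The epithelial list (14 loci) had miR-141-3p and miR-203 lower (3 over the list alone), the ciliated list (8 loci) had miR-449c-5p lower (1 over the list alone), the injury list (10 loci) had both arms of miR-21 lower (2 over the list alone) and the erythroid list (5 loci) had 2 called over the list alone. Under median-ratio rescaling the epithelial and injury lists had 0 called, the ciliated and miR-17-92 lists 1 lower each, the erythroid and leukocyte lists 1 higher and 1 lower each, and the smooth muscle list 3 higher and 4 lower. No striated muscle or other-tissue miRNA was called either way of adjusting. No list was called as a set (smallest adjusted p = 0.4), and the endothelial list's positive median and mean and the erythroid list's positive mean differed in sign from their test. Without the variance trend, or without the tissue sample block, 1 locus was called, miR-3607-5p. With no filter on RPM 36 were called, and under median-ratio rescaling 31, 11 higher and 20 lower.

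Detection with PhiX was 855.5 ± 54 names per library against 859.8 ± 54.6 without it, a difference of -4.3 ± 10.8 (SD, n = 6; lower in 5 of 6; exact sign-flip test, two-sided, p = 0.375), which did not pass; without G it was -8.6 (exact p = 0.0625, the smallest that 5 pairs allow). With PhiX, 113 miRNAs seen without it had 0 reads in all 6 libraries, which allows up to 0.0558 RPM over the group, and 106 showed the reverse. The most abundant of the 113 were miR-4753-5p at 0.133 RPM, miR-4671-5p and miR-4766-3p at 0.102, miR-218-2-3p at 0.0744 and miR-1178 at 0.0667 RPM, as means over libraries. miR-4753-5p had 4 reads and miR-1178 had 2, each in 1 library, so these cannot be set directly against the limit over the group. With at least 5 reads required, a setting chosen after seeing the data, the difference was -10.2 (exact sign-flip test, p = 0.031), and with at least 1 RPM it was 0.3.

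The fourth comparison set the 12-plex against the 3-plex lane, both without PhiX, for tissue samples B to D. miR-3607-5p went from 22.5 RPM ± 8.45 to 1.3 RPM ± 0.507 (SD, n = 3) and fell by 3.32 ± 0.149 on the log2 scale (SE). miR-3653 fell by 1.47 ± 0.188 (SE) from 3.64 RPM ± 0.941 to 0.721 RPM ± 0.625 (SD, n = 3), and miR-1248, in an EIF4A2 host gene (chromosome 3, 186504464 to 186504490), by 1.23 ± 0.145 (SE) from 34.2 RPM ± 53.5 to 6.36 RPM ± 7.88 (SD, n = 3). miR-1291 rose by 1.64 ± 0.177 (SE) from 1.16 RPM ± 0.289 to 5.88 RPM ± 1.91 (SD, n = 3). miR-23c, whose sequence is nearly that of the far more abundant miR-23a and miR-23b so that its reads are of uncertain origin, rose by 1.22 ± 0.176 (SE). Each of the 5 went the same way in 3 of 3 tissue samples, with limma adjusted p values of 5.8e-10 or smaller. These SEs and p values are moderated by the variance trend over loci, and without it none of the 5 was called. miR-1248 went from 96 to 15.4 RPM in D, from 4.41 to 1.88 in B and from 2.2 to 1.74 in C. Leaving out B gave 0.68 log2 for miR-23c, and leaving out D gave -0.57 for miR-1248, which was then not called; without C neither was called.

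The test called 41 loci (17 higher, 24 lower, of 489 tested, 36 names). miR-136-3p rose by 12.5%, miR-30e-3p by 4.3%, miR-30a-3p by 3.76%, miR-182-5p by 3.01%, miR-130a-3p by 2.73%, miR-486-5p by 2.68%, miR-151a-3p by 2.21% and miR-146a-5p by 1.95%, the last turning to -0.000 log2 under median-ratio rescaling. miR-502-5p fell by 33.2% at 2.15 RPM, miR-1247-3p by 32.1% at 3.17 RPM and miR-497-3p by 31.7% at 2.17 RPM, and of the abundant miRNAs miR-103a-3p fell by 4.45%, miR-23b-3p by 4.19%, miR-378a-3p by 3.62% and miR-100-5p by 2.82%. In the smooth muscle and mesenchymal list (21 loci) 5 fell and none rose, among them miR-143-3p, miR-100-5p and miR-199a-3p (6 over the list alone; 8 fell under median-ratio rescaling). In the miR-29 and miR-30 families (20 loci) miR-30d-5p, miR-30a-5p, miR-30a-3p and miR-30e-3p rose and none fell (7 over the list alone), with the median of 0.007 flipping to -0.019 and 0 members called under median-ratio rescaling. In the endothelial list (9 loci) miR-126-5p and miR-130a-3p rose (2 over the list alone), with the median of 0.017 flipping to -0.011 under that scaling and 0 called.

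In the leukocyte list (16 loci) miR-146b-5p and miR-146a-5p rose and both miR-181a-5p loci fell (5 over the list alone; 0 rose and 3 fell under median-ratio rescaling), and in the erythroid list (5 loci) miR-486-5p rose and miR-451a fell (2 over the list alone). The epithelial list (14 loci) had miR-182-5p higher (1 over the list alone), the ciliated list (7 loci) miR-34c-5p lower at -0.13 ± 0.03 log2 (SE, 1 over the list alone) and the injury list (10 loci) miR-21-5p lower (1 over the list alone). miR-34c-5p went from 8.36 to 6.51 RPM in D, from 220 to 209 in C and from 4830 to 4860 in B, so it was not lower in every tissue sample. Under median-ratio rescaling the epithelial list had 2 lower and none higher, and the erythroid, ciliated and injury lists 1 lower each. No let-7, striated muscle, miR-17-92 or other-tissue member was called either way of adjusting, but 6 let-7 loci were lower under median-ratio rescaling. No list was called as a set (smallest adjusted p = 0.55), and the erythroid list's median and mean, and the means of the miR-17-92 and of the miR-29 and miR-30 lists, differed in sign from their tests. Under median-ratio rescaling the medians of the leukocyte, let-7, miR-17-92 and injury lists turned from positive to negative. limma called 0 loci without the variance trend (86 had an unadjusted p under 0.05 with it, and voom called 39), 1 without the tissue sample block, 26 without B and 5 without C. Median-ratio rescaling called 48 loci, 2 higher and 46 lower, against the 17 and 24 above.

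At 12-plex 735.7 ± 16.7 miRNA names were detected per library against 941.7 ± 37.5 at 3-plex (SD, n = 3). The difference was -206.0 ± 24.6 (SD, n = 3; lower in 3 of 3; exact sign-flip test, two-sided, p = 0.25, the smallest that 3 pairs allow), at 0.263 times the reads. Of the miRNAs seen at 3-plex, 265 had 0 reads in the 3 libraries at 12-plex, which allows up to 0.203 RPM over the group, and 25 showed the reverse. The most abundant of the 265 were miR-379-3p at 0.306 RPM, miR-320e at 0.256, miR-1254 at 0.248, miR-505-5p at 0.228 and miR-194-3p at 0.223 RPM. Counting only names with at least 1 RPM gave a difference of -7.0.

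The fifth comparison set the 3-plex lane with PhiX against the one without it, for B to D. Here several let-7 family members rose, with let-7a-5p at 0.05 ± 0.003 log2 (SE, limma adjusted p = 1.4e-20, 66200 RPM ± 2560 to 68300 RPM ± 2670, SD, n = 3), let-7c at 0.05 ± 0.007 and let-7b-5p at 0.04 ± 0.006 (SE). Of 21 let-7 loci (17 names), 10 were called higher and none lower (13 over the list alone), with changes from -0.184 to 0.131 and a mean of 0.012 log2. The family was called as a set by camera at the preset correlation (adjusted p = 0.027), but not with an estimated correlation (camera adjusted p = 0.86). Loci of 1 name repeat reads, as the 3 of let-7a-5p do, which raises the count and which the preset correlation does not allow for. miR-1248 rose by 0.32 ± 0.066 (SE; limma adjusted p = 0.00046) and miR-3607-5p by 0.18 ± 0.05 (SE; limma adjusted p = 0.011), the latter opposite to its fall in the 6-plex PhiX lane. miR-143-3p fell by 1.65% and miR-486-5p by 2.22%. Each named miRNA went the same way in 3 of 3 tissue samples.

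The test called 31 loci (20 higher, 11 lower, of 493 tested, 27 names). miR-335-5p rose by 3.95%, let-7d-5p by 3.24%, miR-98 by 2.77%, let-7e-5p by 2.45% and miR-181b-5p by 2.4%. miR-744-3p fell by 23.7% at 3.67 RPM, miR-375 by 5.11%, miR-148b-3p by 2.89%, miR-27a-3p by 2.61%, miR-24-3p by 2.3%, miR-142-5p by 1.55%, miR-100-5p by 1.53% and miR-30a-5p by 1.03%. In the smooth muscle and mesenchymal list (21 loci) miR-10b-5p rose and miR-143-3p and miR-100-5p fell (3 over the list alone), and in the leukocyte list (16 loci) miR-142-5p fell (4 over the list alone). The epithelial (14 loci; miR-375 lower), erythroid (5 loci; miR-486-5p lower), miR-29 and miR-30 (20 loci; miR-30a-5p lower) and injury (10 loci; miR-21-5p higher) lists had 1 member called, each also over the list alone. No ciliated, striated muscle, endothelial, miR-17-92 or other-tissue member was called either way of adjusting. The medians of the epithelial list, and the means of the striated muscle and miR-17-92 lists, differed in sign from their tests. Under median-ratio rescaling the medians of the epithelial, leukocyte, miR-17-92 and injury lists turned from positive to negative.

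limma called 0 loci without the variance trend or without the block (74 had an unadjusted p under 0.05 with both, and voom called 34), 5 with no filter on RPM and 9 without B. Under median-ratio rescaling 2 loci were called, miR-1248 higher and miR-375 lower, against the 20 higher and 11 lower above, with the let-7 median moving from 0.030 to 0.008 and 0 let-7 loci called. miR-375 was then the 1 locus called in any list. The let-7 set was also not called without the block, without C or without D. The PhiX effects at 6-plex and 3-plex differed at 39 of 506 loci in a limma test of the difference, with miR-3607-5p differing by -2.17 log2 (limma adjusted p = 8.9e-12). The mean number of miRNA names detected was 939 ± 18.1 with PhiX and 941.7 ± 37.5 without it, a difference of -2.7 ± 19.6 (SD, n = 3; lower in 2 of 3; exact sign-flip test, two-sided, p = 0.75, where 3 pairs allow no less than 0.25), and 6.5 without B. With PhiX, 103 miRNAs seen without it had 0 reads in all 3 libraries, which allows up to 0.0533 RPM over the group, and 85 showed the reverse; miR-4640-3p was the most abundant at 0.145 RPM, followed by miR-374c-3p at 0.128, miR-4680-5p at 0.12, miR-4762-5p at 0.0704 and miR-4736 at 0.0575 RPM.

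Tissue sample A was read alone in lane 1 (45 megareads) and in the 12-plex lane (6.01 megareads), 1 library each and so without a test. miR-143-3p had a log2 ratio of -0.13 (12-plex over 1-plex), let-7a-5p one of -0.07 and miR-26a-5p one of 0.04. Across 416 miRNAs the log2 ratios had an SD of 0.229, and across the 59 over 1000 RPM one of 0.089. The extremes were miR-3607-5p at -1.08, with 4.65 RPM and 1.66 RPM, and miR-1291 at 0.94, followed by miR-616-5p at 0.90 and miR-23c at -0.81. There were 1037 names detected in the 1-plex library and 750 in the 12-plex library, 734 of them in both. The most abundant of the 303 seen only at 1-plex was miR-4772-5p at 0.534 RPM, and both libraries had 415 names with at least 1 RPM.

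Tissue samples E to J were also compared with each other over the 24 libraries of lanes 5 to 8. This asks which miRNAs differ between these 6 tissue samples by more than the spread left once shifts of whole lanes are removed. The ciliated epithelial miRNAs, of the miR-34 and miR-449 families that act in the formation of motile cilia, varied most. miR-34c-5p averaged 6710 RPM ± 76.6 in I and 43.1 RPM ± 2.2 in G (SD, n = 4 lanes), and miR-449c-5p averaged 1930 RPM ± 121 in E and 5.74 RPM ± 1.03 in G, a 288-fold range on RPM + 1. All 8 tested ciliated loci differed, with a median SD between tissue samples of 3.24 log2, at percentile 100 of 10000 random lists. The miR-449 loci lie together on chromosome 5 and those of miR-34b and miR-34c on chromosome 11, so the 8 are not separate measures. F and G were the lowest for all of miR-34c-5p, miR-449a, miR-449c-5p and miR-205-5p.

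The epithelial list had 14 of 14 loci called (median SD 1.15, percentile 100). Its loci are not separate measures either. miR-200a and miR-200b lie together on chromosome 1, and F was the highest for miR-141-3p, miR-182-5p and miR-375. In F miR-375 averaged 3390 RPM ± 77.1 against 154 RPM ± 5.49 in J, and miR-182-5p averaged 15200 RPM ± 172 against 1670 RPM ± 32.9 in E (SD, n = 4 lanes). miR-205-5p, a miRNA of basal epithelial cells, averaged 603 RPM ± 14.7 in H and 3.42 RPM ± 1.15 in G, while miR-141-3p averaged 35500 RPM ± 353 in F and 7250 RPM ± 47.1 in J. The striated muscle list had 6 of 6 loci called (median SD 1.34, percentile 99.9), and in F miR-1 was at 28 RPM ± 1.81 against 310 RPM ± 6.62 in E and miR-133a at 18.7 RPM ± 4.07 against 245 RPM ± 4.85. miR-1 and miR-133a stand on 2 loci each, so this list also repeats reads. F also had the lowest miR-143-3p, 97500 RPM ± 2080 against 316000 RPM ± 1660 in E, the lowest miR-10b-5p, 3390 RPM ± 56 against 46000 RPM ± 518 in I, and the highest miR-135b-5p, 101 RPM ± 4.71, and miR-21-5p, 47100 RPM ± 628. As a list, the smooth muscle miRNAs varied less (22 of 22 called, median SD 0.40, percentile 17.7).

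J had the most miR-146b-5p, 141000 RPM ± 1850 against 47300 RPM ± 713 in I, and miR-142-5p, 10800 RPM ± 301 (SD, n = 4 lanes), and the leukocyte list had 16 of 16 called with a median SD of 0.50 (percentile 62.2). G had the most of the erythroid miRNAs miR-486-5p, 39300 RPM ± 853, and miR-451a, 7760 RPM ± 194, and J the least (5 of 5 called, median SD 0.64, percentile 84.8). The endothelial list (9 of 9, median SD 0.44, percentile 38.8) held miR-126-3p, at 4880 RPM ± 50.1 in I and 1220 RPM ± 10.6 in J. The miR-17-92 clusters (18 of 18, median SD 0.52, percentile 72.9) were led by miR-92a-3p, at 13600 RPM ± 188 in F and 3310 RPM ± 68.6 in J. The miR-29 and miR-30 families had 20 of 20 called (median SD 0.50, percentile 65.3), the injury and hypoxia list 10 of 10 (median SD 0.56, percentile 79.2), and the list of miRNAs of other tissues, such as miR-9-5p, 9 of 9 (median SD 0.80, percentile 99.1). These 9 are loci of few names, with miR-9-5p (SD 0.80) on 3 loci and miR-128 (0.27) and miR-138-5p (0.50) on 2 each. Loci of 1 name repeat reads, so the percentile counts miR-9-5p more than once. The let-7 family varied least of the lists, with 20 of 21 called and a median SD of 0.37 (percentile 7.24), and let-7a-5p ranged from 51600 RPM ± 501 in E to 96000 RPM ± 631 in F.

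Other miRNAs among the 20 with the largest SD were miR-184 (SD 1.90 log2, highest in G), miR-190b (1.88, highest in I), miR-31-5p (1.73, lowest in F), miR-92b-3p (1.42, highest in H), miR-5571-3p (1.36, highest in J), miR-200a-5p (1.36, highest in F) and miR-23a-5p (1.33, highest in F). The rest of the 20 were the miR-34b, miR-34c-3p, miR-449a and miR-449b-5p of the ciliated list. Of miRNAs with at least 100 RPM, miR-192-5p varied least, with an SD of 0.10 log2 around 1290 RPM, followed by miR-361-5p (0.15), miR-769-5p (0.16), miR-221-3p, miR-24-3p and miR-27b-3p (0.17 each), miR-27a-3p and miR-28-5p (0.19 each), and miR-23a-3p and miR-181c-5p (0.20 each). The limma F test called 492 of 512 loci over the 4 lanes, at a median SD of 0.466 between tissue samples. The median residual SD, moderated and with shifts of whole lanes removed, was 0.161. It called 486 with the 6-plex lanes alone and 462 with the 9-plex and 12-plex lanes alone, of which 456 were shared (439 expected by chance). Between 1 and 10 RPM, 208 of 233 loci were called at 6-plex and 185 at higher plex, and from 100 RPM all were called in both. These tests describe 6 tissue samples read repeatedly and say nothing of a population.

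**Figure D3:**
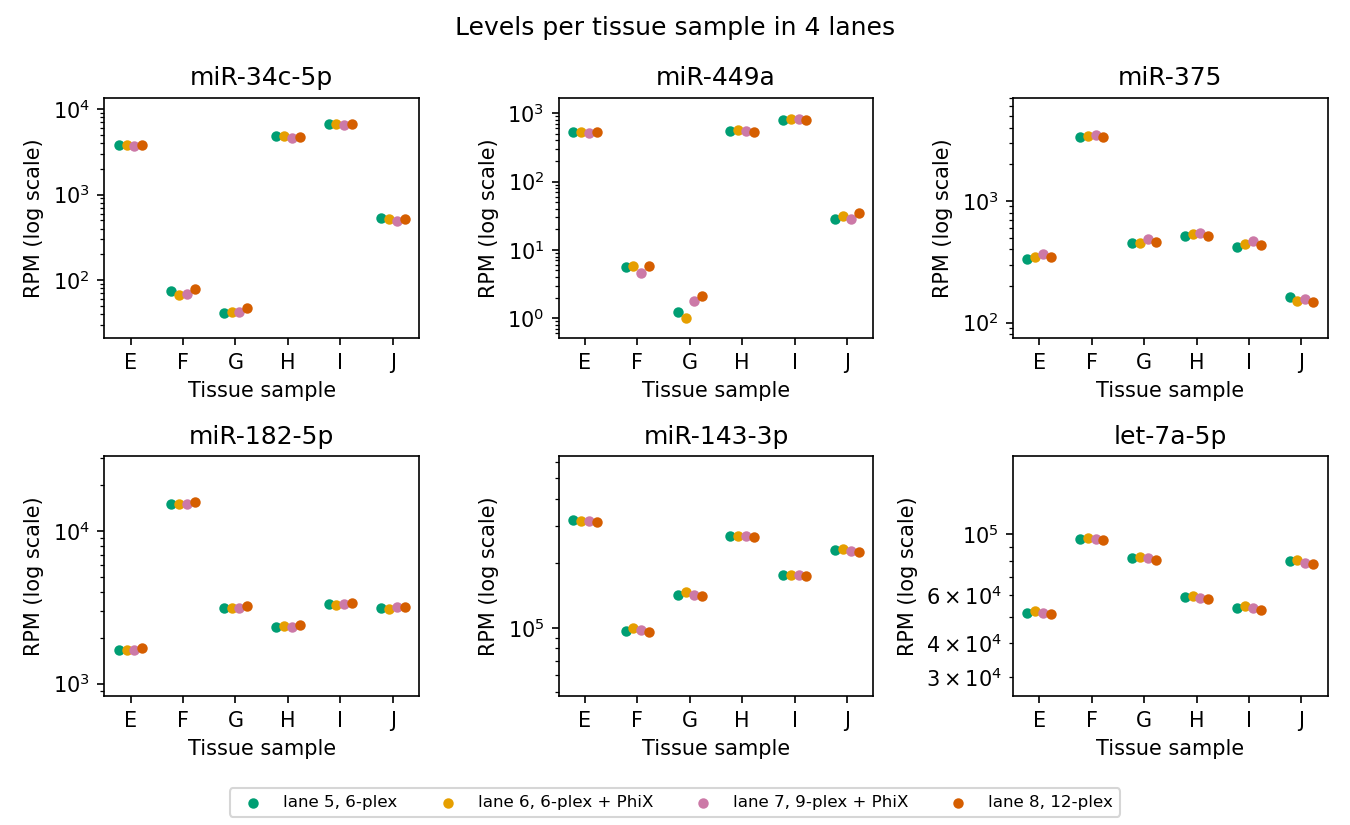
Level of selected miRNAs (RPM, log axis) in tissue samples E to J, each point 1 library, coloured by lane. miR-34c-5p ran from 43.1 RPM ± 2.2 in G to 6710 RPM ± 76.6 in I (mean and SD of 4 lanes).

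Libraries of E to J in lanes 5 to 8 were correlated across miRNAs. Those of the same tissue sample in different lanes (36 pairs) had a mean Pearson's r of 0.9973. Libraries of different tissue samples (240 pairs) had one of 0.964. The difference of 0.0337 had a one-sided permutation p of 1e-05, the smallest that 100000 permutations of the letters within lanes can give. A higher r within a letter could be foreseen, since its libraries are 1 tissue sample and index read again. Differences between tissue samples seen in lane 5 were seen in lane 8 with an r across loci and tissue samples of 0.809 for miRNAs of 1 to 10 RPM, 0.961 for 10 to 100 RPM and 0.996 for 100 to 1000 RPM. The same values were 0.871, 0.977 and 0.998 for lanes 5 and 6, and 0.846, 0.971 and 0.997 for lanes 6 and 7; these r are across loci, which are not independent replicates. With each locus's lane mean removed, the SD of the difference between lanes 5 and 8 fell from 0.353 log2 at 1 to 10 RPM to 0.018 over 1000 RPM.

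**Figure D4:**
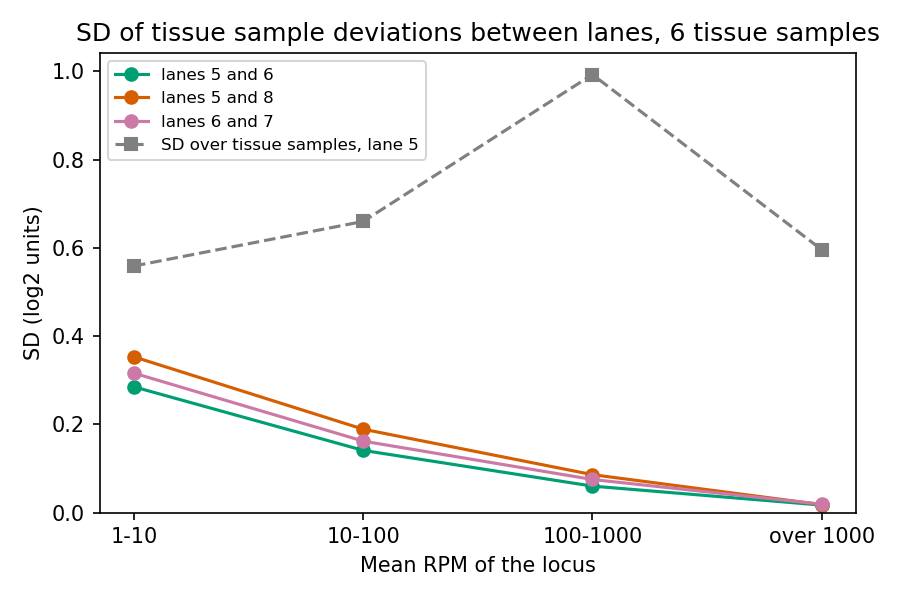
SD of the difference between lanes in each locus's deviation from its lane mean (log2 units), by class of mean RPM, for 3 pairs of lanes and tissue samples E to J, with the SD of the deviations in lane 5 as a dashed line. For lanes 5 and 8 the SD between lanes fell from 0.353 at 1 to 10 RPM to 0.018 over 1000 RPM, where the deviations had SDs of 0.559 and 0.596.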

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

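All tests in this part were chosen after the result was seen, except read depth, hairpin GC content and reads from other libraries. Of 127 groups of libraries checked for a value far from the others, 11 had one, where chance gives about 6.35 (1 in 20).

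The first pattern is the shift between lanes of 4 of the 6 tested miRNA loci on small nucleolar RNA genes (8 in the file), 3 lower and miR-1291 higher at 12-plex than at 6-plex, while miR-664-5p (-0.03) and miR-664-3p (0.06) were not called, and whether such genes are the reason was not tested. The 4 were picked in E to J and then followed in A to D, from lanes with fewer libraries to the 12-plex lane. There 13 of the 16 pairs of tissue sample and locus differed beyond sampling noise, 13 of 13 in the direction of E to J. Median changes were -3.10 (miR-3607-5p), -1.26 (miR-3653), -0.65 (miR-1248) and 1.47 log2 (miR-1291). For miR-1248 only 2 of 4 tissue samples differed beyond sampling noise. Both sets used the same 12-plex lane, and B to D also shared the same 3-plex lane. The 13 pairs are thus not separate tests, and a trait of the 12-plex lane alone could set their direction. Counting error cannot account for miR-3607-5p, whose reads differed beyond sampling noise in 6 of 6 tissue samples (exact binomial test). A PhiX effect of 1 size would not give effects at 6-plex and 3-plex that differed by -2.17 log2. The number of libraries alone would not give the -1.99 between the 2 lanes with 6 libraries, but these lanes also differ in PhiX. With 1 lane per condition, PhiX acting differently by number of libraries cannot be told apart from a difference between lanes. A candidate explanation is a step shared by all libraries of a lane, such as the gel purification of each pool. Which step it was stays open, and no biological explanation was tested, since each pair is 1 tissue sample.

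The second pattern is the set of small shifts of abundant miRNAs shared by comparisons of separate lanes and tissue samples. The log2 changes from 6-plex to 9-plex and from 3-plex to 12-plex had an r of 0.592 and a rho of 0.613 over 61 miRNAs of at least 1000 RPM (permutation p = 1e-05, the smallest possible, 95% range of permuted r from -0.250 to 0.257; miRNAs are not independent replicates), which counting error would not give. Hairpin GC content is argued against, as r was 0.631 after its trend was removed and 0.610 before it (53 miRNAs). That is the GC content of whole hairpins. The GC content of the mature sequences that were read was not tested. A changed share of miR-143-3p moves all other miRNAs of a library alike, so by itself it cannot give an r across them. The r over the 60 others was 0.591 (95% range of permuted r from -0.250 to 0.262). Leaving out 1 of 61 miRNAs could hardly change r, so this value was no separate test. A feature of the miRNAs other than hairpin GC content may set the shifts, and none was tested.

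The third pattern is the lower detection at 12-plex than at 6-plex. Read depth alone may account for it, since 12-plex libraries detected 5.0 more miRNAs on average than 6-plex libraries thinned to their depth (SD 11.5, exact p = 0.406), against a drop of 118 miRNAs (-118.0). Reads assigned from other libraries of the lane would raise detection above the thinned level, and 3 of 6 libraries lay above it, so this cannot be told apart from none at this number of libraries. At 9-plex the libraries detected fewer than their thinned partners by a mean of -14.8 (0 of 6 above, exact p = 0.031), a shortfall that depth does not cover and whose cause was not tested.

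Other results apart are given as values. E had 10.1 megareads (1e6 reads) in lane 7, where the other libraries had 3.03 to 6.51. From no PhiX to PhiX at 6-plex, G gained 17 detected miRNAs where the other tissue samples changed by -11 to -4, F had a log2 difference of -0.007 for miR-145-3p (others -0.146 to -0.132), and G had -0.467 for miR-449c-5p (others -0.172 to -0.028). In log2 level, F stood apart for miR-10b-5p at 11.73 (others 14.71 to 15.49), miR-135b-5p at 6.67 (others 2.70 to 3.98), miR-182-5p at 13.89 (others 10.71 to 11.71) and miR-100-5p at 13.11 (others 11.73 to 12.20). G stood apart for miR-24-3p at 10.79 (others 10.35 to 10.49) and miR-27a-3p at 10.79 (others 10.27 to 10.43), and J for miR-146b-5p at 17.11 (others 15.53 to 16.02). miR-1248 was at 163 RPM in K in lane 7, a tissue sample in no comparison, against 0.625 RPM that 0 reads allow.

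The PhiX effect differed between 6-plex and 3-plex at 39 loci by limma's test of the difference, in different tissue samples. Each condition was 1 lane, so PhiX and lane cannot be separated here, and the p values rest on libraries read again. As the 6-plex minus the 3-plex effect in log2 units, the named differences were 0.10 for miR-1307-5p, 0.09 for miR-125b-5p and miR-423-5p, 0.08 for miR-486-5p, 0.05 for miR-148a-3p, 0.04 for miR-143-3p and 0.02 for miR-146b-5p. They were negative for miR-3607-5p (-2.17), miR-28-5p (-0.13), miR-451a, miR-126-5p, miR-181c-5p and miR-181b-5p (-0.08 each), let-7d-5p (-0.06), miR-98 and miR-142-5p (-0.04 each) and let-7a-5p (-0.03).

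Whether chance could give as many calls was tested by swapping lanes within pairs. For 12-plex and 6-plex the real split, with 53 loci, was the 1 of 32 with as many (highest other 0). It was also 1 of 32 for 9-plex and 6-plex, with 32 loci (highest other 4), and for PhiX at 6-plex, with 61 loci (highest other 0). That is the smallest share 32 splits allow, with no correction over the comparisons. Swapping some pairs puts a lane shift into the residual, which lowers the calls of other splits. Swaps of libraries read again cannot tell whether single lanes differ by chance. For 12-plex and 3-plex (41 loci, highest other 0) and PhiX at 3-plex (31 loci, highest other 0) the 4 splits are too few for a share under 0.05. Splits that did not part every pair were sampled too and gave at most 20 loci. For differences between tissue samples, the real letters, with 492 loci, were the 1 of 100 assignments with as many (highest other 51), the smallest share that 100 assignments allow. Libraries of the same letter are 1 tissue sample read again, so this outcome could be foreseen.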

How the results depend on the processing

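Tests with voom, 1 value per name, locus counts, at least 5 reads, the deposited values and the tissue comparison without F were chosen after the result was seen. Where no cause is given, it was not tested. Of 99 named results under 1450 alternatives, 1041 kept their direction and side of the threshold, 408 lost the call and 1 reversed, miR-146a-5p from 3-plex to 12-plex at -0.000 under median-ratio rescaling. Without the variance trend 95 of the 99 lost their call, and 95 without the block.

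Loci called changed as follows. Without the variance trend there were 3 (12-plex and 6-plex), 0 (9-plex and 6-plex), 1 (PhiX at 6-plex), 0 (12-plex and 3-plex) and 0 (PhiX at 3-plex), and without the block 2, 0, 1, 1 and 0. Median-ratio rescaling gave 12, 31 and 2 (12-plex and 6-plex, PhiX at 6-plex, PhiX at 3-plex), and no filter, with more loci tested, 17, 36 and 5 (9-plex and 6-plex, PhiX at 6-plex, PhiX at 3-plex). Leaving out 1 tissue sample gave 20 (F) to 31 for 9-plex and 6-plex, 5 (C) to 43 (D), with 26 without B, for 12-plex and 3-plex, and 9 (B) to 30 (D) for PhiX at 3-plex. voom called 52, 38, 59, 39 and 34 loci, of which 51, 29, 57, 36 and 28 were shared.

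Lists called at 9-plex went from 0 to 1 under rescaling, with a pseudocount of 5, and without I (0 to 1 over the tissue samples left out), and at 12-plex against 3-plex to 1 without D (0 to 1). The let-7 call of PhiX at 3-plex became 0 with an estimated correlation, under rescaling, without the block, and without C or D (0 to 1). With a mean of at least 10 RPM, 278, 278 and 277 of 279 loci differed between tissue samples (fewer were tested). Over 1000 RPM, r between lanes under rescaling was 0.999 (5 and 6) and 0.998 (5 and 8).

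The difference in miRNAs detected was 6.5 and -0.8 (12-plex and 6-plex), 3.8 and -1.7 (9-plex and 6-plex), and 0.0 and 2.3 (PhiX at 3-plex) at a minimum of 1 and 10 RPM. It was 0.3 and -0.2 (PhiX at 6-plex), and -7.0 and 0.3 (12-plex and 3-plex). With at least 5 reads it was -99.0 (12-plex and 6-plex), -52.0 (9-plex and 6-plex), -10.2 (PhiX at 6-plex, exact p = 0.031), -175.7 (12-plex and 3-plex) and 0.0 (PhiX at 3-plex). Leaving out 1 tissue sample gave -120.8 to -114.8 and -88.0 to -83.8 for the first 2 comparisons, where 5 pairs allow no p under 0.0625, -8.6 (G) to -3.0 for PhiX at 6-plex, and -13.0 to 6.5 (B) for PhiX at 3-plex. Depth limits what 0 reads exclude, down to 0.0533 RPM over a group (PhiX at 3-plex) and only 0.203 RPM at 12-plex (B to D). At 1 to 10 RPM r between lanes was 0.809 to 0.871.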

Other observations

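The tests in this part were chosen after the result was seen.

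In the tissue samples outside E to J, the ciliated cell miRNA miR-34c-5p also varied. It was at 10900 RPM in K, 8310 RPM in L and 4190 RPM in M in the 9-plex lane, and at 4860 RPM in B in the 12-plex lane. In the same 12-plex lane it was at 1450 RPM in O, 842 RPM in A, 209 RPM in C, 57 RPM in N and 6.51 RPM in D.

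Whether index reads of other libraries reached tissue sample A in the 12-plex lane was tested as a hypothesis. The miRNAs used had a mean of at least 50 RPM in the other 11 libraries, at least 20 times that of A in its 1-plex lane. Only miR-449b-5p, at 1 RPM alone and 1.5 RPM in the 12-plex lane, and miR-449c-5p, at 9.48 RPM and 10.3 RPM, met this, and 2 of 2 were higher in the 12-plex lane (exact sign test, p = 0.5). A small crosstalk between indexes may be present, but 2 miRNAs are too few to tell it from counting error.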
